A study of Mus musculus with 18 samples.

How the data were processed

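The data are counts of sequencing reads from RNA purified with translating ribosomes (TRAP) from mouse brain, 1 library per mouse, 18 libraries in all. Per the labels, mice of the silencing experiment received a vector with an shRNA against Ptbp1 or with a scrambled shRNA, and mice of the overexpression experiment a vector with Ptbp1 or a control vector, all carrying mCherry. The labels state that 1 mouse with the Ptbp1 shRNA and 1 mouse with the control vector were left out by the authors because mCherry reads were lacking, which leaves groups of 4 and 5 libraries in silencing and of 5 and 4 in overexpression. The tissue label of every library reads hippocampus, whereas the series' title and design name the entorhinal cortex, and the latter was followed. Groups were taken from the treatment label of each library. The labels give no sequencing batch, sex or litter, and the replicate numbers used here only name libraries, so no samples were paired.

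For each experiment the authors deposited a table of counts per Ensembl gene, and for each library counts per exon bin, the stretches of a flattened annotation that the DEXSeq format numbers within each gene. The deposited counts are whole numbers that were not normalized. Per the submitters' processing notes, STAR 2.5.3a and HTSeq were used with the mouse genome build mm10, with no role stated for either tool. The annotation release and whether reads were counted by strand are not given in the sources used here, so reads of genes that overlap on opposite strands may not be told apart. The gene tables hold 39017 identifiers, of which 37607 matched a symbol, and the exon files 355320 bins. The last 5 lines of each exon file are totals of reads in no single bin, which stayed out of all library sizes and tests. The line of reads in no bin was set against its sum with the bin counts and the line of ambiguous reads. This share was 44.6% ± 0.513 in the scrambled shRNA and 44.9% ± 1.55 in the Ptbp1 shRNA libraries (SD, n = 5 and 4, exact permutation p = 0.667). In overexpression the share was 45.7% ± 1.51 in the control and 46.4% ± 1.43 in the overexpression libraries (n = 4 and 5, exact permutation p = 0.524).

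Coordinates of exon bins were rebuilt from GENCODE release M 21, which uses the same genome build, by flattening those of its transcripts with the lower identifier numbers, since later ones made the bin numbers differ. They were used only for gene identifiers whose number of bins equals that in the deposited files, 89.8% of the 34849 identifiers of single genes found in that release. A bin without coordinates belongs to a gene where the numbers differ. Identifiers that join overlapping genes were tested but not named by rule.

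Each experiment was fitted alone with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test with robust estimates and Benjamini-Hochberg adjustment at 0.05. Standard errors are the size of the log2 fold change divided by the square root of F, and 95% intervals use the total degrees of freedom of the fit. Exon usage was tested with edgeR's diffSpliceDGE, which compares each bin with the other bins of its gene, with the Simes method per gene, and usage is printed as the percent of a gene's bin counts. Levels are CPM, gene counts scaled to the TMM-adjusted library size. Ptbp1 was also compared on the log2(CPM + 0.5) scale by an exact two-sided permutation test over all splits, whose smallest p is 0.0159. The difference between the responses of both experiments was fitted over all 18 libraries with 4 group means and 1 spread. Both experiments have their own controls, so no library is shared between the fold changes correlated across genes.

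Gene lists, designs, alternatives and the naming rule were fixed before the data were examined. The 21 lists hold textbook Ptbp1 splicing targets, microtubule and tau genes, Alzheimer-associated genes, splicing factors, synapse genes, axon guidance genes, immediate early genes, and interferon and antigen presentation genes. They also hold stress genes (p53 and unfolded protein response), nuclear respiratory chain genes, mitochondrially encoded genes, ribosomal proteins and proneural genes. The rest hold markers of superficial excitatory neurons, hippocampus, interneurons, astrocytes, reactive astrocytes, microglia, oligodendrocytes and vessels. Some genes stand in more than 1 list. They were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry as alternatives. Whether splicing targets were over-represented among genes with a called bin was tested with Fisher's exact test, two-sided, against all other genes with several bins tested.

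The naming rule takes Ptbp1, Ptbp2, Ptbp3 and Mapt, then up to 12 rises and 12 falls among called genes with a mean log2 CPM of at least 1. It adds the 10 genes with the smallest p where fewer than 5 pass, and from each list the 2 members with the smallest p. For exon bins it takes, from each of the 15 genes with the smallest p, only the called bin with the smallest p. It adds all called bins of Ptbp1, Ptbp2 and Mapt, and the best bin of each splicing target. Further list members named because they passed when adjusted over the list alone were chosen after their values were seen. Predicted genes were not named. Some genes are not reported here.

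The procedure was tested on data simulated from the means, library sizes and spread of the real libraries, with 100 features changed 2-fold and 100 changed 4-fold. The changed genes and bins were drawn from well expressed ones, so recovery of weakly expressed ones was not tested. Each feature was simulated independently of the others. Of these edgeR recovered 2 and 44 genes with the spread of the silencing experiment (14208 genes tested) and 93 and 100 with that of the overexpression experiment (16237 genes, 14 unchanged ones also called). For exon bins it recovered 0 and 0 (75589 bins) and 49 and 91 (113766 bins, 7 unchanged ones also called). Camera found the 1 list changed in each simulation, and called 1 unchanged list with the silencing spread.

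Alternatives were RLE in place of TMM, no filter or a mean CPM of at least 5, a mean of at least 10 counts per bin, DESeq2 1.42.0, and limma-voom with quality weights or with diffSplice. Others were 1 spread over all 18 libraries, 1 surrogate variable (sva 3.50.0), a glial score of marker genes as covariate, a pseudocount of 0.1 or unscaled library sizes for Ptbp1, and each library left out in turn. Further alternatives, chosen after the data were seen, left out the 2 silencing libraries with the largest share of strongly covered bins at 0, added the number of the mouse as a term, took Ptbp1 out of the splicing targets, or used the glial score, that share or the mitochondrial share as covariates for the lists. No library was close enough to another to be a second deposit of it: libraries of 1 group had Spearman correlations of at most 0.988 over genes. Counting errors rest on reads and not on unique molecules, because molecular identifiers are not described in the labels.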

Results

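The RNA carried by ribosomes of entorhinal cortex layer II neurons was sequenced from 18 mice in 2 experiments, 1 on silencing and 1 on overexpression of Ptbp1. Ptbp1 encodes polypyrimidine tract binding protein 1, an RNA-binding protein that holds many exons out of mRNA and is replaced in neurons by its paralog Ptbp2. The RNA was obtained by translating ribosome affinity purification (TRAP), which captures tagged ribosomes of a chosen cell type together with their mRNA. The layer II neurons of this region are among the first to degenerate in Alzheimer's disease, and the splicing of tau, the product of Mapt, is one process in which Ptbp1 takes part. In the silencing experiment 4 libraries were labelled Ptbp1 shRNA and 5 scrambled shRNA. In the overexpression experiment 5 mice had received a Ptbp1 vector and 4 a control vector. Each library came from 1 mouse, with the entorhinal cortices of both sides pooled.

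The silencing libraries held 34339355 to 46544178 gene counts and the overexpression libraries 18288627 to 39056655. Despite their greater depth, the silencing libraries detected fewer genes, 14841 to 17908 with at least 1 count against 19893 to 21456. Of 56285 exon bins with a mean of at least 50 counts, 1.24% to 8.30% were at 0 in a silencing library and 0.021% to 0.055% in an overexpression library. Libraries of 1 group had gene-level Spearman correlations, across genes, of 0.814 to 0.896 in the silencing experiment and of 0.975 to 0.988 in the overexpression experiment. The common biological coefficient of variation was 90.1% and 22.3%. In data simulated with these spreads, 44 of 100 well expressed genes changed 4-fold were recovered with the silencing spread and 100 of 100 with the overexpression spread.

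The first question was whether the vectors moved Ptbp1 itself. The libraries labelled Ptbp1 shRNA had 6.57, 0.101, 0.588 and 13.1 CPM of Ptbp1 (counts scaled to library size), and those labelled scrambled shRNA 3.38, 0.93, 6.72, 0.349 and 9.11. The mean log2 difference was -0.18 (SE 1.26, n = 4 and 5, exact two-sided permutation p = 0.921), so a reduction of Ptbp1 was not detectable. Without 1 library at a time the difference lay between -0.93 (without Ptbp1 shRNA replicate 4) and 0.56 (without Ptbp1 shRNA replicate 2), and it was above 0 also without Ptbp1 shRNA replicate 3 (0.28) or scrambled shRNA replicate 3 (0.12) or 5 (0.22). Directions in the silencing experiment therefore belong to the label of the libraries and not to a measured fall of Ptbp1. Overexpression raised Ptbp1 from 17.2, 13.5, 9.96 and 12.3 CPM in the control libraries to 136, 143, 158, 129 and 118 CPM. That is a log2 difference of 3.34 (SE 0.172, n = 5 and 4), or 10.1-fold, with an exact two-sided permutation p of 0.0159, the smallest that splits of 9 libraries can give.

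**Figure D1:**
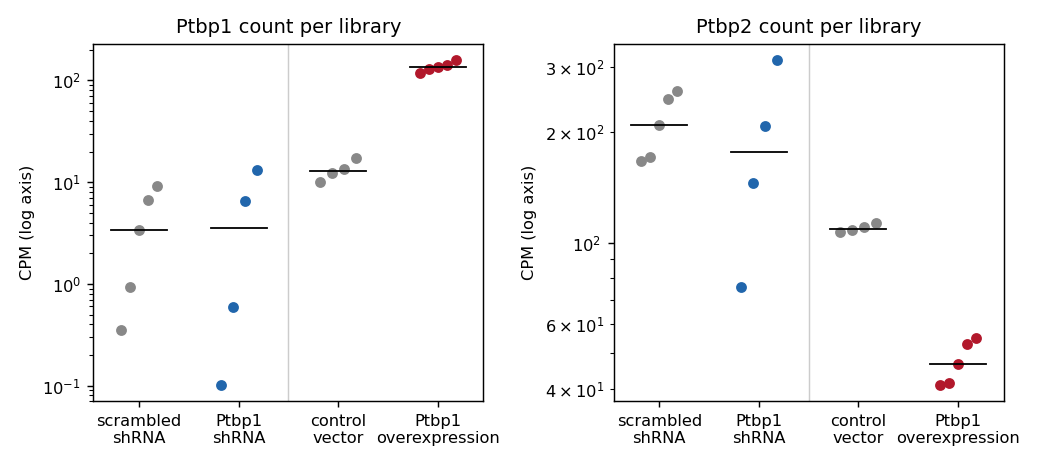
CPM of Ptbp1 (left) and Ptbp2 (right) on log axes, 1 point per library, with a line at the group median, for the scrambled shRNA (n = 5), Ptbp1 shRNA (n = 4), control vector (n = 4) and Ptbp1 overexpression (n = 5) libraries. Ptbp1 ranged from 0.101 to 13.1 CPM in the libraries labelled Ptbp1 shRNA, within and beyond the scrambled range of 0.349 to 9.11, whereas all 5 overexpression libraries (118 to 158 CPM) were above all 4 control libraries in Ptbp1 and below them in Ptbp2.

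In the libraries labelled Ptbp1 shRNA, no gene passed the test, and the genes with the smallest p are given as not passing. Cdkn1a, the cell cycle inhibitor induced by p53, had 142 ± 82.5 CPM in the libraries labelled Ptbp1 shRNA against 22.3 ± 7.59 in the scrambled ones (SD, n = 4 and 5; log2 fold change 2.67, SE 0.42). Cplx2, a complexin that clamps synaptic vesicle fusion, had 625 ± 134 against 1469 ± 218 CPM (-1.23, SE 0.20), and Kalrn, a guanine nucleotide exchange factor of dendritic spines, 376 ± 92.9 against 860 ± 78.2 (-1.19, SE 0.20). Kcnip3, a calcium-binding partner of potassium channels, had 193 ± 53 against 540 ± 114 CPM (-1.48, SE 0.24). Nars, the asparaginyl-tRNA synthetase, had 358 ± 28 against 142 ± 28.9 CPM (1.33, SE 0.21), and Cxadr, the receptor of coxsackie viruses and adenoviruses, 216 ± 54.8 against 43.8 ± 21.6 (2.31, SE 0.38). The others of the 10 genes with the smallest p were Ubxn2b (-1.86, SE 0.26), Luzp1 (1.54, SE 0.25), Pgbd5 (-2.17, SE 0.36) and the Arf GTPase activator Asap1 (-1.73, SE 0.29). All 10 had an adjusted p of 0.0625 in edgeR's quasi-likelihood test, and for each of them all 4 libraries labelled Ptbp1 shRNA lay beyond all 5 scrambled libraries, which chance gives for a share of 0.0159 of all genes and which genes picked by their p mostly show. Of 14656 genes tested, edgeR called 0 (27 shared the smallest adjusted p of 0.0625), with 1639 at an unadjusted p under 0.05 where 733 are expected. DESeq2 called 705 genes and limma-voom with quality weights 84, and edgeR called 1775 when all 18 libraries shared 1 spread. Leaving out Ptbp1 shRNA replicate 4, Ptbp1 shRNA replicate 2 or scrambled shRNA replicate 5 gave 5, 1 and 2 calls.

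The genes fixed as always reported had wide intervals in this experiment. Mapt had 142 ± 65.3 CPM in the libraries labelled Ptbp1 shRNA and 191 ± 46.4 in the scrambled ones (SD, n = 4 and 5; log2 fold change -0.43, 95% interval -1.10 to 0.24). Ptbp2 had 185 ± 101 and 210 ± 42.0 CPM (-0.18, -0.92 to 0.56), and the third paralog Ptbp3 62.8 ± 26.9 and 52.4 ± 14.1 (0.26, -0.49 to 1.01). The edgeR adjusted p-values were 0.664, 0.902 and 0.853, and that of Ptbp1 was 0.961 (log2 fold change 0.31, -2.43 to 3.05).

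Genes of cell stress, p53 and the unfolded protein response rose as a group in the libraries labelled Ptbp1 shRNA. Of 26 members measured, 23 were higher, with a median log2 fold change of 1.01, and 9 had an unadjusted p under 0.05, all of them higher. None was called over all genes, and 5 passed when adjusted over the list alone. These were Cdkn1a, already named, and Atf3, a transcription factor of acute stress (12.4 ± 10.2 against 0.0461 ± 0.0684 CPM). The others were Chac1, which degrades glutathione in the unfolded protein response (14.2 ± 2.13 against 2.84 ± 1.08), and the endoplasmic reticulum chaperone Dnajb9 (243 ± 58 against 102 ± 41.8). The last was Mdm2, the ligase that limits p53 (240 ± 98.1 against 121 ± 33.9). The list passed limma's camera test (adjusted p = 2.2e-08 over 21 lists), kept its call with an estimated correlation (adjusted p = 0.0052) and by fry (adjusted p = 0.000186), and was called without any 1 of the 9 libraries. In the overexpression experiment 16 of 26 members were higher (median 0.08, camera adjusted p = 0.0832; adjusted p = 0.53 with an estimated correlation), with 0 members passing when adjusted over the list alone. An unadjusted p under 0.05 was found for 4, all higher. The list passed camera there with 1 surrogate variable (adjusted p = 0.0263), without Ptbp1 overexpression replicate 1 (0.0239) and, chosen after the data were seen, with the share of strong bins at 0 as covariate (0.0212). There the member with the smallest p was Cdkn1a, at 74.0 ± 7.37 against 57.7 ± 5.38 CPM, higher in 5 of 5 libraries than in any control (log2 fold change 0.36, edgeR adjusted p = 0.678).

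**Figure D2:**
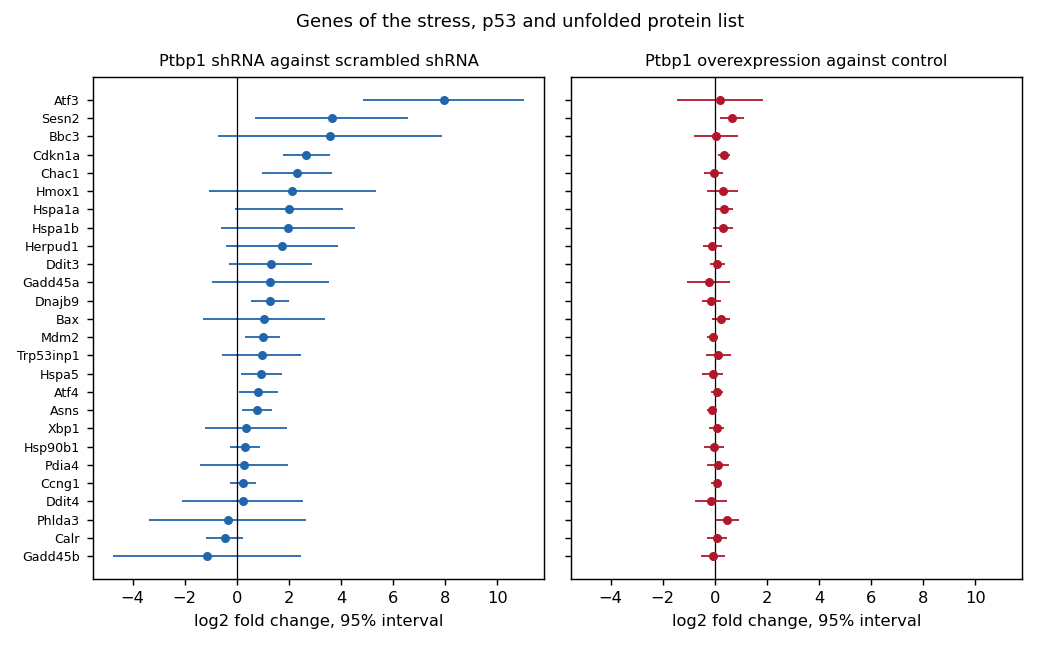
Log2 fold change with its 95% interval, on a shared axis, of the 26 measured genes of the stress, p53 and unfolded protein list, for the libraries labelled Ptbp1 shRNA against scrambled shRNA (left, n = 4 and 5) and Ptbp1 overexpression against control vector (right, n = 5 and 4). On the left 23 genes lie above 0, with a median of 1.01, and on the right 16 do, with a median of 0.08.

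Of the other 20 lists, camera with its preset correlation called a pair in the silencing experiment, and neither call held with an estimated correlation. The 13 mitochondrially encoded mRNAs, which code for respiratory chain subunits, were all higher (median log2 fold change 0.54, adjusted p = 0.0332; adjusted p = 0.516 with an estimated correlation), with mt-Co3 at 32.1 ± 12.3 against 13.8 ± 6.62 CPM. The mitochondrial share counts all genes whose symbol starts with mt-, so it is not limited to these mRNAs. It was 0.53% to 0.95% in the libraries labelled Ptbp1 shRNA, 0.18% to 0.54% in the scrambled ones and 0.03% to 0.11% in the overexpression experiment. Of 44 neuronal and general splicing factors, 33 were lower (median -0.24, adjusted p = 0.0332; adjusted p = 0.348 with an estimated correlation). Matr3 and Hnrnpa1 had 120 ± 37.7 against 236 ± 50.3 and 94.0 ± 20.9 against 174 ± 40.4 CPM. Each list had 0 members passing when adjusted over the list alone. The mitochondrial call was lost without the 2 least evenly covered libraries (adjusted p = 0.138) and with the share of strong bins at 0 as covariate (0.107), both chosen after the data were seen. That of the splicing factors was lost with 1 surrogate variable (0.0605) or, chosen after, the mitochondrial share (0.0746). Among single libraries, the mitochondrial call was lost without scrambled shRNA replicate 1 (adjusted p = 0.296) or Ptbp1 shRNA replicate 2 (0.253) or 4 (0.07). That of the splicing factors was lost without Ptbp1 shRNA replicate 1 (0.122) or 4 (0.138) or scrambled shRNA replicate 1 (0.0578), 2 (0.0727) or 5 (0.0644).

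Neuronal lists did not pass in the silencing experiment, though single members did when adjusted over the list alone. In the synapse list (28 of 40 lower, camera adjusted p = 0.0866) these were the vesicle SNARE Vamp2 (964 ± 462 against 2261 ± 224 CPM) and the adhesion molecule Nrxn3 (136 ± 6.83 against 346 ± 149). In the list of superficial excitatory neuron markers (11 of 14 lower, 0.0734) they were Rorb, Camk2a and Mef2c. In the list of microtubule and tau genes (24 of 50 lower, median 0.03 and mean 0.05, with camera pointing down, 0.881) the motor subunits Dync1h1 (191 ± 102 against 55.2 ± 12.6) and Kif5c were higher and the microtubule-binding Mapre2 and Map1b lower. Of the Alzheimer-associated genes (16 of 25 lower, 0.449) the adaptor Cd2ap passed so, with 168 ± 108 against 25.2 ± 25.6 CPM. Of the axon guidance genes (25 of 37 lower, 0.119) the secreted guidance cue Sema3a did, with 70.3 ± 42.3 against 228 ± 68.8. No member passed when adjusted over the list alone among the textbook Ptbp1 splicing targets (17 of 28 lower, 0.449), immediate early genes (15 of 23 higher, 0.635) and interferon and antigen presentation genes (11 of 20 lower, median -0.03 and mean 0.41, with camera pointing up, 0.0902). The same holds for nuclear respiratory chain genes (21 of 42 higher, 0.635), ribosomal proteins (32 of 46 higher, 0.171) and proneural genes (13 of 17 lower, 0.103).

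Markers of other cells and of the hippocampus did not pass as lists in the silencing experiment either. Of the hippocampal markers, Tdo2 passed when adjusted over the list alone, at 0.0489 ± 0.0813 against 5.88 ± 4.81 CPM. Its lowest scrambled library was also at 0. The camera adjusted p-values were 0.119 for hippocampal markers (6 of 9 lower) and 0.119 for interneurons (11 of 13 lower). They were 0.338 for astrocytes (8 of 13 lower, with Atp1b2 passing so, at 106 ± 51.2 against 303 ± 45.4 CPM) and 0.119 for reactive astrocytes (5 of 6 higher). For the remaining markers they were 0.449 for microglia (3 of 4 lower), 0.879 for oligodendrocytes (6 of 8 lower, median -0.15 but mean 0.34) and 0.396 for vessels (4 of 5 higher).

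For exon usage, the libraries labelled Ptbp1 shRNA gave 1 call among 83164 bins of 8593 genes. It was bin 010 of Dph6, a gene of diphthamide synthesis. The bin is a 163 bp non-coding transcript segment at mm10 chromosome 2, 114545729 to 114545891. It held 1.59% ± 1.45 of the gene's bin counts against 0.00643% ± 0.0144 in the scrambled libraries (SD, n = 4 and 5; log2 relative usage 7.83, edgeR adjusted p = 0.00485, higher in 4 of 4 libraries). The call was lost without Ptbp1 shRNA replicate 2 (adjusted p = 0.52) and without scrambled shRNA replicate 1 (0.0854), 2 (0.114), 3 (0.122) or 4 (0.0642). It was also lost with limma's voom and diffSplice (0.702) and, chosen after the data were seen, with the mouse number as a term (0.953) or without the 2 least evenly covered libraries (0.297). The log2 relative usage was then 5.85, 7.07 and 7.96. Only 1630 bins had an unadjusted p under 0.05 where 4158 are expected, limma's voom with diffSplice called 8 others, and 0 of 23 Ptbp1 splicing targets had a called bin (Fisher's exact p = 1; 0 of 440 bins when adjusted over the list alone). In simulated data with this spread 0 of 100 bins changed 4-fold in level were recovered. Each was the first tested bin of its gene, and the true median log2 relative usage was 1.33. A change in usage of about that size was therefore not detectable in such bins.

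On overexpression of Ptbp1 edgeR called 7 genes, with 6 higher and 1 lower, of which Plppr3 is uncertain because it overlaps Ptbp1. All 5 treated libraries lay beyond all 4 controls for each of the 7, which genes picked by their p mostly show. Ptbp2, the neuronal paralog, fell from 109 ± 2.54 to 47.5 ± 6.51 CPM (SD, n = 4 and 5; log2 fold change -1.20, SE 0.10, edgeR adjusted p = 7.81e-05). Cd2ap, an adaptor of actin and endocytosis and a risk gene of Alzheimer's disease, rose from 9.06 ± 1.65 to 29.6 ± 6.26 CPM (1.70, SE 0.18, adjusted p = 0.000953). The class IIa histone deacetylase Hdac7 rose from 1.94 ± 0.378 to 6.16 ± 1.40 (1.66, SE 0.24, adjusted p = 0.0173). Pdlim7, an actin-associated scaffold, rose from 23.9 ± 1.02 to 46.3 ± 5.56 CPM (0.96, SE 0.11, adjusted p = 0.0019). Lss, the lanosterol synthase of cholesterol synthesis, rose from 23.6 ± 2.33 to 44.4 ± 3.28 (0.91, SE 0.11, adjusted p = 0.0019). Ptbp1 itself had a log2 fold change of 3.36 (SE 0.15, adjusted p = 5.48e-08). Mapt stayed at 328 ± 22.8 against 313 ± 25.7 CPM (0.07, 95% interval -0.10 to 0.24, adjusted p = 0.974) and Ptbp3 at 21.3 ± 3.42 against 19.9 ± 2.19 (0.10, -0.19 to 0.40, adjusted p = 0.974). Of 16480 genes tested, 788 had an unadjusted p under 0.05 where 824 are expected, DESeq2 called 39 genes and limma-voom 8. The call of Hdac7 was lost without Ptbp1 overexpression replicate 2 (adjusted p = 0.0821) or 3 (0.0696) or control replicate 2 (0.11), 3 (0.132) or 4 (0.0689). It was also lost with 1 surrogate variable (0.0524) or the glial score (0.0969), at log2 fold changes of 1.66 and 1.48. No gene was called when all 18 libraries shared 1 spread, where the log2 fold changes stayed close (Ptbp1 3.37, Ptbp2 -1.20, Cd2ap 1.71 and Hdac7 1.67).

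The remaining call was Plppr3, a lipid phosphatase-related membrane protein. Its count went from 9.93 ± 3.03 to 59.5 ± 3.92 CPM (n = 4 and 5; log2 fold change 2.58, SE 0.18, edgeR adjusted p = 6.41e-06). In mm10, Ptbp1 lies on the plus strand of chromosome 10 from 79854427 to 79864771 and Plppr3 on the minus strand from 79860475 to 79874634, and whether reads were counted by strand is not given in the sources used here. The 2 Plppr3 bins inside Ptbp1 had a log2 fold change of 3.95 (95% interval 3.63 to 4.26), and the 29 bins outside it 0.20 (-0.37 to 0.76). Within Ptbp1, the 45 coding and 5′ bins had a log2 fold change of 3.75 (3.38 to 4.13), and the 4 bins of the 3′ UTR -0.27 (-1.0 to 0.45).

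**Figure D3:**
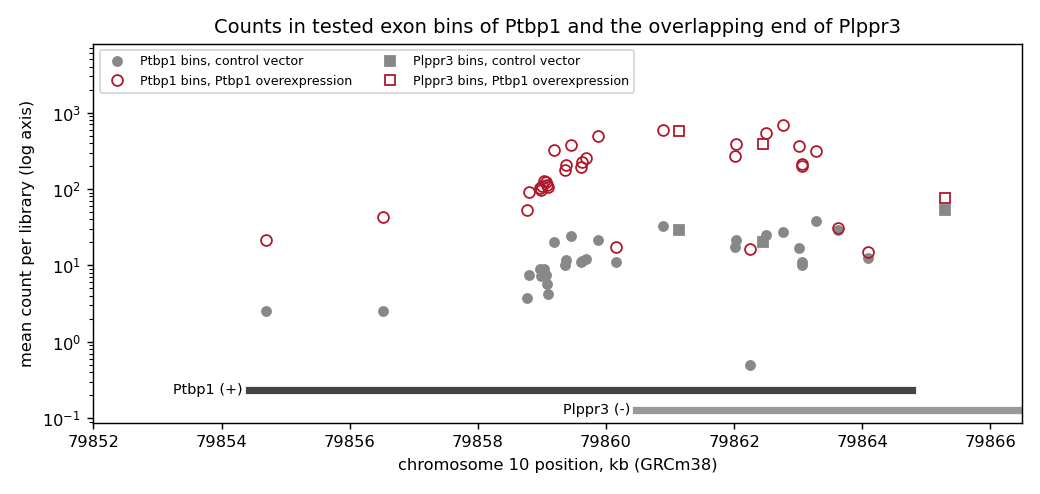
Mean count per library (log axis) of each tested exon bin of Ptbp1 (circles) and Plppr3 (squares) against its position on chromosome 10 in kb, for control vector (filled, n = 4) and Ptbp1 overexpression (open, n = 5) libraries, with the extent and strand of each gene drawn as bars and means under 0.5 drawn at 0.5. The 2 Plppr3 bins inside Ptbp1 are higher on overexpression like the Ptbp1 coding bins, while the last Ptbp1 bins, in the 3′ UTR, are nearly level.

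On overexpression the relative usage of 40 exon bins in 30 gene identifiers was called, 27 higher and 13 lower, bins of Ptbp1 and Plppr3 included. A UTR bin of the kinesin light chain Klc1 (bin 030, mm10 chromosome 12, 111806315 to 111806711) rose from 0.131% ± 0.0921 to 1.17% ± 0.187 of the gene's bin counts (SD, n = 4 and 5; edgeR adjusted p = 4.58e-31, log2 relative usage 3.11). A bin of 3 coding bases of the synaptic kinase Camk2b (bin 022, chromosome 11, 5982759 to 5982761) rose from 0.0502% ± 0.0153 to 0.428% ± 0.0608 (adjusted p = 7.17e-20, 3.07). A partly coding bin of synaptopodin, Synpo, an actin-binding protein of dendritic spines (bin 004, chromosome 18, 60593991 to 60596488), rose from 0.31% ± 0.162 to 5.84% ± 2.10 (adjusted p = 8.22e-16, 4.07). Bin 009 of Snap91, a clathrin assembly protein, rose from 0.12% ± 0.0269 to 0.645% ± 0.0885, and bin 022 of the dystrobrevin Dtna from 15.4% ± 0.374 to 29.4% ± 1.45. Higher usage was also called for coding bins of the tropomyosin Tpm1 (bin 021, chromosome 9, 67032466 to 67032541), of the proton pump subunit Atp6v1h (bin 007, chromosome 1, 5101070 to 5101123) and of the actin regulator Abi2 (bin 005, chromosome 1, 60447260 to 60447406). So it was for a UTR bin of the septin Sept6 and for bins of pyruvate kinase Pkm and the actin monooxygenase Mical2. The partly coding 3′ bin of Ptbp2 (bin 001, chromosome 3, 119718742 to 119720460) fell from 32.5% ± 5.21 to 14.7% ± 3.20 (adjusted p = 5.11e-06, -1.17). A UTR bin of the splicing factor Srsf1 (bin 015, chromosome 11, 88050096 to 88050410) fell from 15.4% ± 2.12 to 7.29% ± 1.35 (adjusted p = 1.73e-05, -1.08). For each of these bins all 5 treated libraries lay beyond all 4 controls, which bins picked by their p mostly show.

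**Figure D4:**
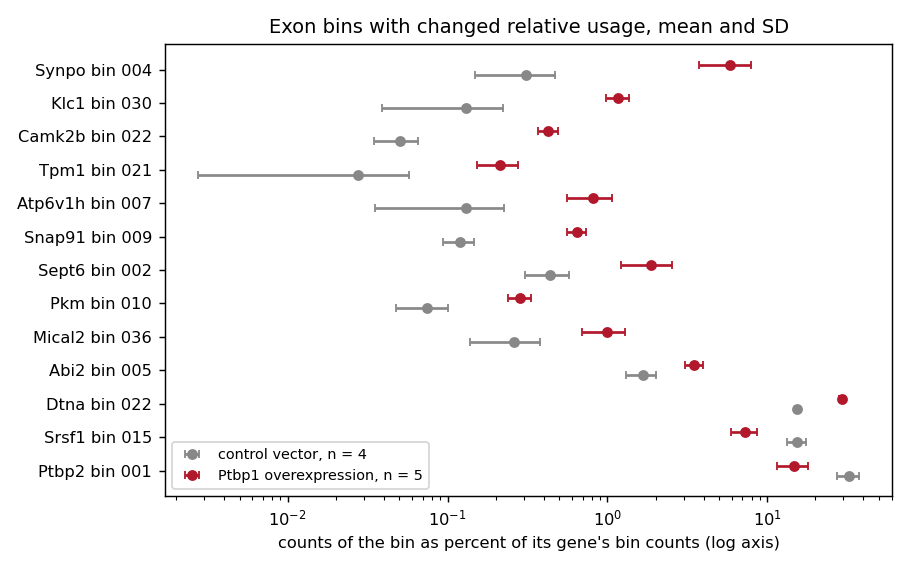
Counts of an exon bin as percent of all bin counts of its gene (log axis), mean and SD for control vector (grey, n = 4) and Ptbp1 overexpression (red, n = 5) libraries, for the 13 of the 15 named genes other than Ptbp1 and Plppr3. Usage was higher in 11 bins, from 0.31% to 5.84% in Synpo bin 004 at the top, and lower in Srsf1 bin 015 and Ptbp2 bin 001. A lower bar that would reach 0 is shortened to stay on the log axis (Tpm1).

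In Ptbp1 3 bins were called, all of them lower in share and none lower in mean count. UTR bins 046 (chromosome 10, 79863425 to 79863818) and 047 (79863819 to 79864359) fell from 6.70% ± 2.15 to 0.435% ± 0.114 and from 3.02% ± 0.915 to 0.192% ± 0.112 of the gene's bin counts (n = 4 and 5). Their mean counts were 29.5 and 12.5 in control and 31 and 14.8 in treated libraries. The coding bin 034 (79860126 to 79860194) fell from 2.83% ± 1.49 to 0.23% ± 0.157, with mean counts of 11 and 17.6. Bin 003 of Plppr3, outside Ptbp1, fell in share from 49.8% ± 11 to 7.75% ± 3.31 while its mean count was 53.5 and 77. Of the 117580 bins of 10274 genes tested, 1613 had an unadjusted p under 0.05 where 5879 are expected, 28 genes passed by the Simes method and limma's voom with diffSplice called 59 bins. The strongest calls outside the naming rule, chosen after their values were seen, lay in an identifier that joins Map4, a microtubule-binding protein related to tau, with another gene. Its bins 008 to 012 rose, bin 011 from 1.68% ± 0.322 to 9.95% ± 1.38, and bin 007 fell from 62.1% ± 1.21 to 40.5% ± 3.36 (edgeR adjusted p = 0.0377).

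Textbook splicing targets of Ptbp1 were over-represented among the genes with a called bin on overexpression. Pkm, Tpm1, Tpm3, Ptbp1 and Ptbp2 made 5 of 27 targets tested (18.5%), against 25 of 10247 other genes (0.244%), an odds ratio of 92.2 (95% interval 25.3 to 277, Fisher's exact p = 1.15e-08). The targets had more bins per gene (608 bins tested in 27 genes) than all genes (117580 in 10274), which this test does not take into account. With genes called by the Simes method, the same 5 targets stood against 23 of 10247 (Fisher's exact p = 7.99e-09). The coding bin 037 of Tpm3 (chromosome 3, 90091013 to 90091091) fell from 1.75% ± 0.281 to 0.846% ± 0.367 (edgeR adjusted p = 0.0182, lower in 5 of 5 libraries). When adjusted over the list alone, 8 bins of the same 5 genes passed. Without Ptbp1, which the vector encodes (left out after the data were seen), 4 of 26 targets had a called bin (Fisher's exact p = 7.33e-07). The other 22 targets had none, among them Mapt, whose bin with the smallest p was bin 011 (1.38% ± 0.914 against 0.935% ± 0.174, adjusted p = 1). Mapt bin 026 is exon 10 (chromosome 11, 104318157 to 104318249), whose inclusion sets the number of microtubule-binding repeats of tau, and was chosen for its known splicing after the values were seen. It held 1.44% ± 0.278 of the gene's bin counts on overexpression and 1.37% ± 0.217 in control libraries (log2 relative usage 0.06, SE 0.26, adjusted p = 1). In the silencing experiment it held 2.20% ± 2.60 in the libraries labelled Ptbp1 shRNA and 0.507% ± 0.422 in the scrambled ones (1.85, SE 1.41, adjusted p = 1). There the coding bin 028 of Mapt moved alike (1.87, SE 1.40), so the value is not particular to exon 10. The coding bins 024 and 030 moved by 0.37 (SE 1.27) and 0.26 (SE 1.27).

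On overexpression camera with its preset correlation called 6 of the 21 gene lists, and none of them was called with an estimated correlation, where the smallest adjusted p was 0.53, or by fry. Of the interferon and antigen presentation genes, 24 of 25 were higher, with a median log2 fold change of 1.08 (camera adjusted p = 6.47e-10; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 9 passed, among them the transcription factors Stat2 (23.8 ± 4.96 against 15.4 ± 3.34 CPM), Irf7 (2.83 ± 1.51 against 0.856 ± 0.369) and Irf9 (10.04 ± 4.46 against 4.85 ± 1.18). Microglial markers were higher in 10 of 11 cases (median 0.69, adjusted p = 0.00238; adjusted p = 0.53 with an estimated correlation), at low levels. P2ry12, which passed when adjusted over the list alone, had 1.32 ± 0.616 against 0.381 ± 0.181 CPM, and Csf1r 5.78 ± 1.65 against 5.08 ± 0.827. All 13 mitochondrially encoded mRNAs were lower (median -0.37, adjusted p = 2.29e-05; adjusted p = 0.677 with an estimated correlation), with mt-Co1 at 60.8 ± 18.8 against 90.6 ± 22.1 CPM. Ribosomal protein genes were higher in 42 of 46 cases (median 0.11, adjusted p = 2.29e-05; adjusted p = 0.83 with an estimated correlation). Synapse genes were lower in 33 of 40 cases (median -0.13, adjusted p = 0.000603; adjusted p = 0.715 with an estimated correlation), led by Snap25 at 13090 ± 1531 against 16240 ± 1977 CPM. Axon guidance genes were lower in 28 of 39 cases (median -0.10, adjusted p = 0.0419; adjusted p = 0.83 with an estimated correlation). With the number of the mouse (1 to 5 or 6 to 10) as a term, chosen after the data were seen, the interferon, mitochondrial and microglial lists were still called. The ribosomal, synapse and axon guidance lists were not (adjusted p = 0.0844, 0.128 and 0.99). The microglial call was lost at a mean CPM of at least 5 (adjusted p = 0.965), and the synapse and axon guidance calls with 1 surrogate variable (0.0505 and 0.899). With covariates chosen after the data were seen, the glial score ended the microglial (0.132) and axon guidance (0.282) calls. That score is made in part of the microglial markers themselves, so it is no separate test of their list. The mitochondrial share ended the synapse (0.201), ribosomal (0.112) and axon guidance (0.863) calls, and the share of strong bins at 0 that of axon guidance (0.457). The axon guidance call was lost without any 1 of Ptbp1 overexpression replicates 1 (0.884), 2 (0.122) and 3 (0.406) and control replicates 2 (0.0697), 3 (0.143) and 4 (0.124), and the ribosomal call without control replicate 2 (0.146).

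The remaining lists were not called on overexpression. The camera adjusted p-values were 0.604 for the textbook splicing targets by expression (18 of 29 lower, median -0.04 but mean 0.08, with Ptbp1, Ptbp2, Ppp3cb and Flna passing when adjusted over the list alone) and 0.232 for microtubule and tau genes (31 of 50 lower). They were 0.912 for Alzheimer-associated genes (15 of 29 higher, with Cd2ap passing over the list alone) and 0.723 for splicing factors (26 of 44 higher, median 0.03 but mean -0.02 and camera pointing down, with Ptbp2 passing so). Next came 0.628 for immediate early genes (13 of 24 lower), 0.205 for nuclear respiratory chain genes (29 of 42 higher) and 0.628 for proneural genes (12 of 19 higher). For markers they were 0.723 for superficial excitatory neurons (7 of 14 higher), 0.723 for the hippocampus (6 of 12 higher, median and mean -0.01, with camera pointing up) and 0.45 for interneurons (8 of 14 higher). For glia and vessels they were 0.476 for astrocytes (10 of 15 higher, with S100b at 17.7 ± 5.34 against 11.6 ± 2.95 CPM), 0.205 for reactive astrocytes (4 of 6 higher), 0.628 for oligodendrocytes (10 of 13 higher) and 0.45 for vessels (9 of 13 higher). Apart from those named, 0 members of these lists passed when adjusted over the list alone.

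The last question was whether genes answered silencing and overexpression in different ways, tested as the difference of both responses over all 18 libraries. Ptbp2 differed by -1.02 (overexpression minus silencing, SE 0.38, edgeR adjusted p = 0.203), Ptbp1 by 3.05 (SE 1.25, adjusted p = 0.252), Mapt by 0.51 (SE 0.32, adjusted p = 0.506) and Ptbp3 by -0.15 (SE 0.38, adjusted p = 0.923). Of 17779 genes, 40 were called, 19 with the higher and 21 with the lower response on overexpression, and 0 of the 40 were called within either experiment. Among them were Ubxn2b (2.0, SE 0.26, adjusted p = 0.00349), Nars (-1.27, SE 0.20, adjusted p = 0.0174) and Cplx2 (1.14, SE 0.20, adjusted p = 0.0223). So was Cdkn1a (-2.31, SE 0.44, adjusted p = 0.0394). The response on overexpression was within 0.25 of 0 for 33 of them, and 16 had opposite signs. The common dispersion in this fit, 0.556, lies between 0.812 in silencing and 0.0498 in overexpression, so the spread of the silencing libraries may be understated. For Ubxn2b and Nars the SE of the difference was no larger than that of the silencing response alone (0.26 and 0.21). The count of 40 also depended on single libraries. It was 1 without control replicate 4 or Ptbp1 overexpression replicate 5, at most 14 without any other overexpression library, and up to 174 (without Ptbp1 shRNA replicate 4). It stayed within 1.5 times of 40 only without scrambled shRNA replicate 1, 3 or 4.

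For exon usage the difference of responses was called for 115 of 138200 bins in 95 gene identifiers, 50 with the higher and 65 with the lower response on overexpression (12410 at an unadjusted p under 0.05, 6910 expected). Of the genes with a bin called on overexpression, Ptbp1 and Plppr3 left out, 14 had that bin tested in the silencing experiment, and 7 of them moved the opposite way there (50%, exact 95% binomial interval 23% to 77%, exact binomial p = 1). Across 14367 genes tested in both experiments, the log2 fold changes had a Pearson correlation of 0.032 and a Spearman correlation of 0.040. These are correlations across genes, which are not independent replicates.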

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

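Of the tests in this part, those on sequencing depth and on captured molecules were chosen only after the result was seen, and the one on the Ptbp1 level was fixed before.

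Some libraries lay far from the others of their group. Scrambled shRNA replicate 5 had 14841 genes with a count where the others of its group had 16418 to 17013. It also had 7.61% of the strongly covered exon bins at 0, against 1.54% to 2.56%, and 76.9 CPM of Ptbp3, against 42.7 to 51.7. Scrambled shRNA replicate 1 had a mean log2(CPM + 0.5) of 4.44 over the mitochondrially encoded genes, against 5.68 to 6.07. Among the libraries labelled Ptbp1 shRNA, replicate 3 had 71.1 CPM of Ubxn2b against 42.5 to 47.2, and replicate 4 had 515 CPM of Kalrn against 319 to 342. In all, 6 of 88 groups of values held such a library, where 4.4 are expected by chance at 1 in 20.

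In the silencing experiment edgeR called 0 genes, with 1639 at an unadjusted p under 0.05, where DESeq2 called 705 and limma-voom 84. Sequencing depth argues the other way, since the median was 40.4 M gene counts in the silencing libraries and 23.3 M in the overexpression libraries. Few captured molecules per library are a candidate explanation: even the best covered silencing library had 1.24% of the strongly covered bins at 0, above every overexpression library (at most 0.055%). A Ptbp1 that was not reduced stays open, because the 95% interval of its log2 fold change reaches from -2.43 to 3.05 and so holds both a strong fall and a rise. Other splits say nothing here, since a count of 0 is reached by all 100 of them whatever the data (highest other 0).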

How the results depend on the processing

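The settings that leave out 2 libraries, add the number of the mouse, use covariates for the lists or take Ptbp1 out of the splicing targets were chosen after the data were seen, and the others before. Where no value shows it, the cause of a difference was not tested. In the silencing experiment the 0 called genes became 11 without a filter, 40 at a mean CPM of at least 5, 705 with DESeq2, 84 with limma-voom and quality weights. They became 1775 with all 18 libraries in 1 fit (where the overexpression libraries lower the shared spread) and 6 with 1 surrogate variable, and 0 to 5 without 1 library at a time. The 1 exon bin called there became 6 at a mean of at least 10 counts, 8 with voom and diffSplice and 0 with the mouse number as a term. It became 0 without the 2 least evenly covered libraries (Ptbp1 shRNA replicate 2 and scrambled shRNA replicate 5) and 0 to 3 without 1 library. Its 3 called lists became 1 with an estimated correlation, 1 with fry, 5 without these 2 libraries, 5 with the glial score, 5 with the mitochondrial share and 1 to 5 without 1 library. The mitochondrial list turned downward with the mitochondrial share as covariate (adjusted p = 0.0373), a covariate that includes the same genes.

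In the overexpression experiment the 7 called genes became 39 with DESeq2 and 0 with all 18 libraries in 1 fit (where the silencing libraries raise the shared spread). Its 6 called lists became 0 with an estimated correlation, 0 with fry, 3 with the mouse number and 3 with the mitochondrial share. Its axon guidance list turned upward with 1 surrogate variable (adjusted p = 0.899) and with the mouse number (0.99). The 40 genes whose responses differ became 871 with DESeq2 and 275 without the 2 least evenly covered libraries, and 1 to 174 without 1 library, and the 115 bins became 1015 without those 2 libraries. The correlation of fold changes moved from 0.032 to -0.013 with DESeq2 and to 0.076 at a mean CPM of at least 5.

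The Ptbp1 level in silencing ranged from -0.933 to 0.561 without 1 library. Among single genes without a call, the log2 fold change changed sign in silencing for Ptbp1 (-0.02 with limma-voom, and -0.76 to 0.84 without 1 library), Ptbp3 (-0.16 with the glial score, and -0.07 to 0.44) and Ptbp2 (-0.56 to 0.08). It also did for Pvalb (1.30), P2ry12 (0.01) and Ermn (-0.95) with the glial score, of which P2ry12 and Ermn are themselves a part. The same holds for Ermn without 1 library (-0.49 to 3.02) and for Slco1a4 (-0.11 without the 2 libraries, -0.14 with the mouse number). In overexpression it did so for Ptbp3 (-0.03 with 1 surrogate variable) and Inhba (-1.57 to 0.06 without 1 library). The exon bins called on overexpression stayed between 35 and 41 under every alternative except voom with diffSplice (59), and the test of splicing targets kept its side. No paired analysis was possible because the replicate numbers only name libraries and belong to different mice in each group. Depth limits the low genes, and in the silencing libraries bins without any count occur even where the mean is at least 50.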

Other observations

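Of the tests in this part, those on Plppr3, on the division by mouse number, on covariates for the stress list and on splits for the interferon list were chosen only after the result was seen, and the others were fixed before.

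In the overexpression experiment more genes were called along the numbers the mice carry in the labels than for the vector, though with smaller fold changes. This division was examined after it had given the most calls among 100 splits of these libraries, so its count is a selected maximum. Between the 5 libraries of mice 6 to 10 (2 with Ptbp1) and the 4 of mice 1 to 5 (3 with Ptbp1), edgeR called 396 genes, 358 higher and 38 lower in the former, with a median log2 fold change of 0.55, where the vector's calls had sizes of 0.91 to 3.36. For exon bins this division called 2 and the vector 40. With the vector as a term, 194 were called, 188 of them the same genes. Among those named first by p were the sodium channel genes Scn2a (0.68, SE 0.10, adjusted p = 0.0139) and Scn1a (0.80, SE 0.14, adjusted p = 0.0142). So were the layer II marker Reln (0.74, SE 0.12, adjusted p = 0.0139) and the guidance genes Sema3a (0.69, SE 0.10, adjusted p = 0.0139) and Robo2 (0.69, SE 0.11, adjusted p = 0.0139). Of the lists called by camera with its preset correlation, the axon guidance (adjusted p = 2.46e-11) and synapse lists (6.62e-08) were higher and the ribosomal protein (4.94e-10), interneuron (3.53e-05) and vessel lists (0.000105) lower in mice 6 to 10. In that order they had adjusted p = 0.322, 0.322, 0.42, 0.167 and 0.463 with an estimated correlation, so none was called that way. The mitochondrially encoded list was also called higher (adjusted p = 0.000823, median 0.44), and the nuclear respiratory chain (0.00836), proneural (0.0418) and interferon lists (0.0471, median -0.83) lower, with adjusted p = 0.622, 0.628, 0.322 and 0.663 with an estimated correlation. The mitochondrial and interferon differences run along this division as well as with the vector, which 3 of the 4 libraries of mice 1 to 5 and 2 of the 5 of mice 6 to 10 carried. The labels say nothing of what these numbers stand for. In the silencing experiment edgeR called 0 genes for the same division, with 718 at an unadjusted p under 0.05 where 733 are expected. There camera called the interferon (adjusted p = 0.00539, median -0.83) and stress lists (adjusted p = 0.018, median -0.45) lower in mice 6 to 10, both with adjusted p = 0.857 with an estimated correlation. Of the 4 libraries labelled Ptbp1 shRNA 3 came from mice 1 to 5, and with the mouse number as a term the stress list was still called higher in them (limma camera adjusted p = 3.3e-07).

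Cd2ap was higher in both experiments, with a log2 fold change of 1.70 on overexpression (edgeR adjusted p = 0.000953, higher in 5 of 5 libraries) and of 2.74 in the libraries labelled Ptbp1 shRNA (adjusted p = 0.127, higher in 4 of 4). Bin 005 of Ptbp2, named outside the rule after its values were seen, is a coding exon of 34 bases at mm10 chromosome 3, 119724612 to 119724645. It held 4.78% ± 0.931 of the gene's bin counts on overexpression and 4.47% ± 0.715 in control libraries (SD, n = 5 and 4). Its log2 relative usage was 0.12 (SE 0.24, edgeR adjusted p = 1), while the count of the gene fell.

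Plppr3 was called with a log2 fold change of 2.58 on overexpression. More Plppr3 transcript is hard to reconcile with its bins outside Ptbp1, which moved by 0.20, with an upper 95% limit of 0.76, below 1.29, the midpoint between 0 and the change of the gene. The values are consistent with reads of Ptbp1 being counted in the Plppr3 exons that overlap it on the other strand, where the 2 bins inside Ptbp1 moved by 3.95, close to the 3.75 of the coding bins of Ptbp1. No biological explanation other than more transcript was tested.

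Stress, p53 and unfolded protein genes rose in the libraries labelled Ptbp1 shRNA by a median log2 fold change of 1.01. With the share of strong bins at 0 as a covariate the median was 1.03 (limma camera adjusted p = 1.13e-07, before adjustment 5.39e-09). That share was 4.17% ± 2.99 in the libraries labelled Ptbp1 shRNA and 3.03% ± 2.59 in the scrambled ones (SD, n = 4 and 5). As it differed little, adding it could change little, and uneven coverage that it does not measure stays open. With the glial score as a covariate the median was 0.94 (limma camera adjusted p = 2.67e-06, before adjustment 1.27e-07). That score holds astrocyte, microglial and oligodendrocyte markers only, and its difference between the groups is not given here. Other cell types therefore stay open. The share of mitochondrial reads did not account for the rise (median 0.95, limma camera adjusted p = 6.6e-06, before adjustment 3.15e-07). Of 100 splits of the 9 libraries only the real one gave a camera p as small for this list, and the smallest other was 5.92e-08. The list had the smallest p of all 21, and the smallest p of any list was not compared across splits. Chance is therefore unlikely but not excluded. A response to this shRNA apart from Ptbp1 may be the source, and so may a fall of Ptbp1 that these counts do not resolve. Both stay untested, since the design holds no group that separates them.

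Other splits of the libraries show how firm each count is. The 7 genes called on overexpression were matched by 3 of 100 splits, the real one included. They hold Ptbp1, which the vector encodes, and Plppr3, which overlaps it, so the count does not exclude chance for the other genes. The highest other count, 396, came from the split by mouse number, which was examined only after these splits were seen. As the highest of the splits tried, that count is no separate test of a structure of the samples. With the mouse number as a term all 7 genes were called again. The 40 exon bins called on overexpression were matched by 1 of 40 splits, the real one (highest other 19). The 40 genes whose responses differ were matched by 1 of 100 (highest other 14). Chance is thus unlikely for each count as a whole, but not excluded for single calls. The bins include those of Ptbp1 and Plppr3. The count of 40 genes comes from a fit that may understate the silencing spread, and it fell to between 1 and 14 without 1 overexpression library. Chance cannot be excluded for the 1 exon bin in silencing (22 of 40 splits, highest other 6), the 3 lists in silencing (30 of 100, highest other 7), the 6 lists on overexpression (43 of 100, highest other 11) or the 115 bins whose responses differ (8 of 24, highest other 263). Taken alone, the interferon list on overexpression had a camera p of 3.08e-11, and 12 of 100 splits gave one as small, down to 3.66e-17.

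If Ptbp1 acts on the bins called on overexpression, its silencing would be predicted to move them the opposite way. Of 14 such bins tested in the silencing experiment 7 did, or 50% (exact 95% interval 23% to 77%, exact binomial p = 1). The test decides nothing, since Ptbp1 was not measurably lower in the silencing libraries and the interval is wide.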
